A study of Arabidopsis thaliana with 4 samples.

How the data were processed

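Total RNA from rosette leaves of 3-week-old Col-0 and AAF-OX plants was labelled with biotin and hybridised to Affymetrix arrays by the authors, per the labels' protocols, with 2 arrays per genotype. Only the deposited value table was used. Its values are intensity values on a linear scale (MAS5 signals per the submitters' processing notes, version not given in the sources used here), deposited with each array scaled to a 2%-trimmed mean of 500, as the values themselves show (500.04 to 500.05 on each array). Detection calls were not used here, and array scanner files were not analysed here. The precision is limited by the number of arrays, 2 per group.

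The table has 22810 probe sets, of which 64 are controls and were left out of the tests. Signals were taken as log2(signal + 50), with the pseudocount set in proportion to the trimmed mean, and probe sets with a mean of at least 100 over the 4 arrays were kept (13592 tested, 9154 left out). Folds are on the scale of signal plus 50, which understates changes of dim probe sets. Probes were named from the platform's gene table: 13513 probes had 1 gene, 503 had several and were not named, and 8730 of the 22746 probe sets that are not controls are unnamed here. Of the probes with 1 gene, 13436 matched a locus of the TAIR10.1 gene table, which gave the names and the order of genes along chromosomes. No coordinates are given, since no genome build is named for the probes. The locus of AAF was taken from knowledge of the study, not from the labels.

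Groups came from the sample titles. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided, Benjamini-Hochberg over the probe sets tested, threshold 0.05). The planned model has genotype alone (2 residual degrees of freedom), and the paired model adds the replicate number as a block (1 residual degree of freedom and 10.7 borrowed). The series states that 2 independent sets of arrays were run, and the replicate numbers were taken to mark these sets. The check made for this pairing was the correlation of same-numbered arrays' deviations from their group means, which was 0.856. Nothing in the labels says whether the sets came from separately grown plants, so p-values measure the spread between these arrays, which may be technical. The blocked fit also leaves out the difference between sets, and most of its error estimate is borrowed across probe sets. An SE can therefore be smaller than the disagreement between a gene's own pairs, as for AT3G28220 (SE 0.23, pairs at -2.19 and -0.84). An adjusted p over all probe sets, an SE or a difference per gene in the text is that of the blocked fit unless the planned fit is named.

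The 28 gene lists (391 memberships, 48 tested) were tested gene by gene, and by camera with a preset correlation of 0.01 where at least 5 members were tested, which only the photosynthesis list had. With several probe sets per gene, the one with the highest mean was used, and 3 list members whose identifier and symbol disagreed were left out. Named genes were AAF, then, among named probe sets past the threshold that moved the same way in both pairs, the 12 largest increases and 12 largest decreases, with places not filled in the planned fit taken by separate groups at an unadjusted p under 0.01. Each list added up to 4 members past the threshold, or else the 2 with the smallest unadjusted p. The planned model, filter, pseudocount, lists and a naming rule for that model were set before the data were examined. That rule asked for AAF-OX arrays both above or both below both Col-0 arrays. Naming from the paired model, by the same direction in both pairs, was not part of it. Some genes named that way, such as AT4G16260 and COR15A, lack separate groups. The set contrast used the same model with the set in place of the genotype.

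The chromosome 1 segment was bounded by a least-squares change point on the differences of pair 1, over genes in chromosome order, and then measured in pair 2. Its median was compared with 10000 random gene sets of the same size and signal level, drawn from nuclear genes outside it. The alternatives tried were pseudocounts of 1 and 100, no filter or a mean of at least 250, quantile normalization, median centring, no intensity trend, the block, each array left out in turn, an estimated correlation and the mean of probe sets for lists, and crossed pairs. Added after seeing the data were the same settings together with the block, control probe sets kept and the brightest hundredth left out. Leaving out the named genes of the chromosome 1 segment was added then too. The fits were tested on simulated data for AAF-OX against Col-0 over 13592 probe sets, with 50 probe sets changed by each of 4 sizes. The blocked fit recovered 36% at a log2 of 0.585, 96% at 1, 100% at 2 and 80% at -1, with 20 false calls among 176, and the fit without the block recovered 0%. A simulated segment ending at gene 305 was found to end at gene 304.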

Results

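Transcripts were measured in rosette leaves of 3-week-old Arabidopsis thaliana plants grown in cycles of 16 h light and 8 h dark. Wild-type Col-0 was compared with AAF-OX, a line that overexpresses AAF, and each genotype was hybridised to 2 Affymetrix arrays (n = 2 per group, 4 arrays in all). The arrays came from 2 separately run sets, each taken here to hold 1 Col-0 and 1 AAF-OX array, called pair 1 and pair 2 here. The value table gives 22810 probe sets per array. The median signal was 180.2 for Col-0 and 176.6 for AAF-OX in pair 1, and 169.9 and 169.0 in pair 2. Log2 signals correlated across probe sets at r = 0.982 within pair 1 and 0.979 within pair 2, against 0.895 to 0.908 for arrays of different pairs.

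The comparison of AAF-OX with Col-0 asks how leaf transcripts of 3-week-old plants differ where AAF expression is raised. AAF, taken here as locus AT1G66330, rose from 760 to 7442 in pair 1 and from 1337 to 7706 in pair 2. Its group means were 1048 ± 408 in Col-0 and 7574 ± 186 in AAF-OX (SD, n = 2), a 7.19-fold difference on the scale of signal plus 50 (log2 2.85 ± 0.15, SE; limma's adjusted p = 2.53e-06 with the sets as a block).

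At the pseudocount of 50, the largest increases in named genes, above that of AAF, were in the defensins PDF1.2 and PDF1.2b, antifungal peptides and standard markers of the jasmonate and ethylene defence response. PDF1.2 went from 1204 to 16932 in pair 1 and from 200.5 to 1661 in pair 2 (log2 3.27 ± 0.18, adjusted p = 3.37e-06). PDF1.2b went from 1339 to 12046 and from 90.6 to 1849 (log2 3.44 ± 0.15, adjusted p = 4.95e-07), read from a probe set of the type that can bind transcripts of related genes. Further increases were in AT4G16260, of the beta-1,3-glucanase family (log2 2.58 ± 0.22, adjusted p = 0.000113), AT3G23550, of the MATE efflux transporter family (log2 1.72 ± 0.15, adjusted p = 0.000114), and the osmotin-like gene OSM34 (log2 1.70 ± 0.27, adjusted p = 0.0105). AT4G23680, of a family of small ligand-binding proteins related to major latex proteins, rose from 79.0 ± 16.8 to 282.7 ± 39.9 (SD, n = 2; log2 1.37, adjusted p = 0.006). The glutaredoxin-family gene AT4G15680 rose by a log2 of 1.29 (adjusted p = 0.0262), with 0.70 in pair 1 and 1.88 in pair 2. The other 4 of the 12 largest increases, AT1G02470, AT1G05340, AT1G10340 and AT1G10410, had log2 differences of 1.09 to 1.27 and all lie near the start of chromosome 1, among genes that were mostly higher in AAF-OX. Outside the rule that chose these genes, and picked after its values were seen, the chitinase-family gene CHI was also higher (log2 1.05 ± 0.18, adjusted p = 0.0156). In pair 2 the Col-0 signals of AT4G16260, OSM34 and CHI were only 13.2, 16.8 and 9.9, so the size of their increase depends on the pseudocount. With a pseudocount of 1 they were 3.64, 2.53 and 2.02, and AT4G16260 then ranked above PDF1.2 (3.43) and AAF (2.91).

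Among named genes, the strongest decrease was in AT3G02630, of the stearoyl-acyl carrier protein desaturase family, which introduces double bonds into plastid fatty acids. It fell from 767 to 161.8 in pair 1 and from 1482 to 222.4 in pair 2, 4.66-fold lower (log2 -2.22 ± 0.16, adjusted p = 1.82e-05). AT3G28220, a TRAF-like family member, followed (log2 -1.51 ± 0.23, adjusted p = 0.00875), with -2.19 in pair 1 and -0.84 in pair 2. AT2G01060, of the MYB-like transcription factors, had -1.17 ± 0.17 (adjusted p = 0.0054). The cold-responsive chloroplast proteins COR15A and COR15B were lower by log2 differences of -1.10 ± 0.12 (adjusted p = 0.00118) and -0.84 ± 0.13 (adjusted p = 0.00865). AT4G30650, of a low-temperature and salt responsive family, differed by -0.73 (adjusted p = 0.006). The rest of the 12 largest decreases in named genes were in AT2G33850 (-0.99), the copper amine oxidase family gene AT1G31690 (-0.86), the serine carboxypeptidase-like scpl50 (-0.81), the glycine-rich protein gene AT4G29030 (-0.81), the pectin methylesterase inhibitor family gene AT5G62360 (-0.73) and the pectin lyase-like gene AT1G60590 (-0.73), with adjusted p from 0.00308 to 0.0389.

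**Figure D1:**
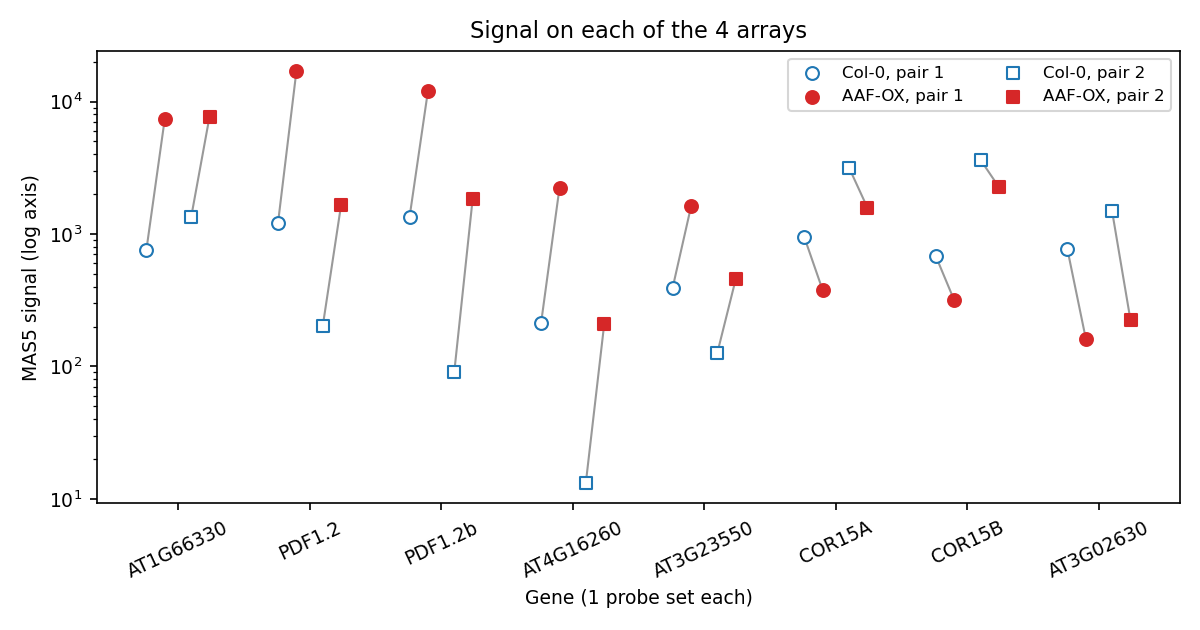
MAS5 signal (vertical log axis) of 8 genes on each of the 4 arrays, with open symbols for Col-0, filled symbols for AAF-OX, circles for pair 1, squares for pair 2 and a line joining the arrays of a pair. AAF-OX lay above Col-0 in both pairs for AT1G66330, PDF1.2, PDF1.2b, AT4G16260 and AT3G23550 and below it for COR15A, COR15B and AT3G02630, while the level of PDF1.2 in AAF-OX was 16932 in pair 1 and 1661 in pair 2.

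With the sets as a block, limma called 210 of 13592 probe sets at an adjusted p under 0.05 (1.55%), of which 182 were higher and 28 lower in AAF-OX, and 34 of the higher and 7 of the lower ones differed at least 2-fold. The planned fit, on genotype alone, leaves the difference between sets in the error and called 0 (limma; 117 probe sets at an unadjusted p under 0.05, 680 expected by chance, smallest adjusted p 1), AAF included. In that fit AT1G66330, AT4G23680, AT3G02630, AT1G10410 and AT1G10140 had separate groups and the unadjusted p values (limma) of 0.000512, 0.00272, 0.0028, 0.00505 and 0.00906. AT1G10140 had a log2 difference of 0.85 (0.82 in pair 1 and 0.87 in pair 2). Without any test, 20 probe sets were at least 2-fold higher in both pairs and 1, that of AT3G02630, at least 2-fold lower, against 8 and 1 when each Col-0 array was set against the AAF-OX array of the other set. The blocked fit has 1 residual degree of freedom and borrows information on the error across probe sets. On simulated data 11.4% of its calls were false, more than the threshold of 0.05 allows for, so calls near the threshold are less certain. The count of the blocked fit was 18 without the filter on dim probe sets and 21 without the intensity trend of the variance. PDF1.2, PDF1.2b, AT1G66330, AT4G16260, AT3G23550, AT3G02630 and COR15A passed in all 10 alternatives run with the block, and every other gene named above lost its call in at least 1 of them.

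**Figure D2:**
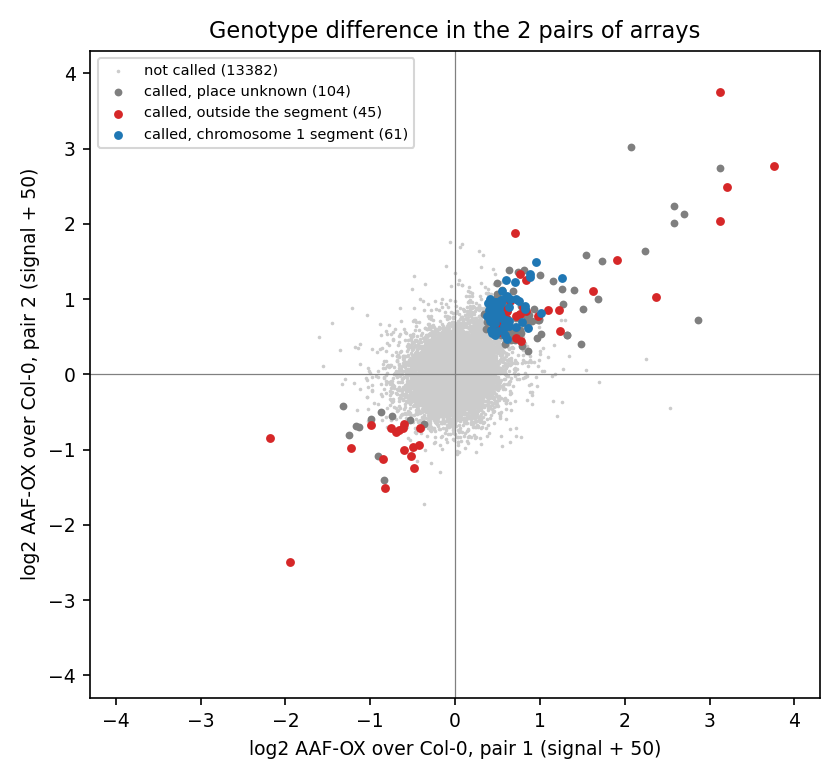
Log2 difference between AAF-OX and Col-0 (signal plus 50) in pair 1 (horizontal axis) and pair 2 (vertical axis), 1 point per probe set, coloured by whether limma called it with the sets as a block and by its place in the genome. The 182 higher calls lie in the upper right and the 28 lower calls in the lower left, and over all probe sets the differences of the pairs correlated at r = 0.301.

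Of 28 gene lists fixed beforehand, 22 had at least 1 gene among the probe sets that were named and tested, and they held 46 such genes. The lists have 391 memberships in all, so most members were not examined. In the jasmonate and wounding list, 2 of 3 tested genes were higher (PDF1.2 and PDF1.2b), and the thionin gene THI2.1 had a log2 difference of -0.16 (adjusted p = 0.892). In the cold response list, 2 of 3 were lower (COR15A and COR15B), and COR47, also the single tested gene of the abscisic acid and water deficit list, had -0.19 (adjusted p = 0.602). STZ, a zinc finger repressor of stress responses in the lists for reactive oxygen and for touch and handling, was higher (log2 0.61, adjusted p = 0.044), from 273.1 to 504.7 in pair 1 and from 2736 to 3720 in pair 2, a call lost in 5 of the 10 alternatives run with the block. The other reactive oxygen gene, AT2G21640, had -0.50 (adjusted p = 0.414), and adjusted over the list alone both genes passed. PYK10 and NAI2, a beta-glucosidase and a protein of endoplasmic reticulum bodies on the root list, had -0.54 and -0.58 and passed when adjusted over the list alone (limma's adjusted p = 0.0027 and 0.00312) but not over all probe sets (limma's adjusted p = 0.0679 and 0.108). For the other lists, the calls adjusted over the list alone were the same as those over all probe sets.

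No tested gene of the senescence list passed, but only 4 of its 22 members were tested, so most of its markers were not examined. Of its 4 tested genes, the regulators WRKY53 and WRKY22 had log2 differences of 0.37 and -0.33, and 0.366 was the smallest adjusted p in the list. The chlorophyll b reductase gene NOL had 0.22, and the starvation genes AT3G15450 and AKINBETA1 had 0.15 and 0.17. All 8 tested photosynthesis genes, of 39 on the list, failed the test, with LHCB4.1 at -0.20 and LHCB4.2 at -0.20. Their median was -0.10, and camera gave an unadjusted p of 0.0648 with the block and 0.0824 without it (p = 0.533 and 0.524 with an estimated correlation). With 1 array left out of the planned fit, the median was -0.33 without AAF-OX replicate 2 and -0.22 without Col-0 replicate 1. It was 0.00 without Col-0 replicate 2 and 0.08 without AAF-OX replicate 1. Leaving out 1 array mixes the set difference into these values, and the 8 genes had a median 0.32 higher in set 2. Within pairs, their differences ran from -0.39 to -0.02 in pair 1 and from -0.20 to 0.09 in pair 2. Among 3 antioxidant genes, the copper chaperone gene CCS had 0.30 and the glutathione reductase gene GR -0.20. Single tested genes were GSTU20 for glutathione transferases (-0.22), GRX480 for salicylic acid and defence (0.16), GI for the evening clock (-0.25), AUR1 for cell division (-0.29) and DFR for anthocyanin synthesis (-0.20). Values in the remaining lists were RTE1 -0.26 and EIN3 -0.03 for ethylene, BCAT4 -0.10 and UGT74B1 -0.04 for glucosinolate synthesis, HAT2 0.25 and IAA29 -0.15 for auxin, ARR15 -0.36 and RR16 -0.06 for cytokinin, and AT4G34270 0.20 and PEX4 -0.07 among the reference genes. None of these passed. The lists for the morning clock, flowering time, floral organs, shoot meristem, heat shock and phosphate starvation had no named and tested gene.

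The calls were unevenly placed. Of the 7149 measured and named nuclear genes, the first 305 on chromosome 1, from AT1G01080 to AT1G11280, held 61 of the 89 named higher calls and 0 of the 17 named lower ones. The other 6844 genes held 28 higher and 17 lower calls, and 93 higher and 11 lower calls could not be placed. The median log2 difference over the 305 genes was 0.38 in pair 1 and 0.53 in pair 2, where the rest of the genome had -0.03 in both, and 268 of them (87.9%) were higher in AAF-OX in both pairs against 21.7% of the rest. AT1G66330 itself lies outside this stretch. This stretch was noticed in the data and was not a planned comparison. Without its named genes, limma with the sets as a block called 117 probe sets, 90 higher and 27 lower. Probe sets with no known place stayed in. All 117 were also called with the stretch included, so at most 28 of the 90 are known to lie outside it.

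**Figure D3:**
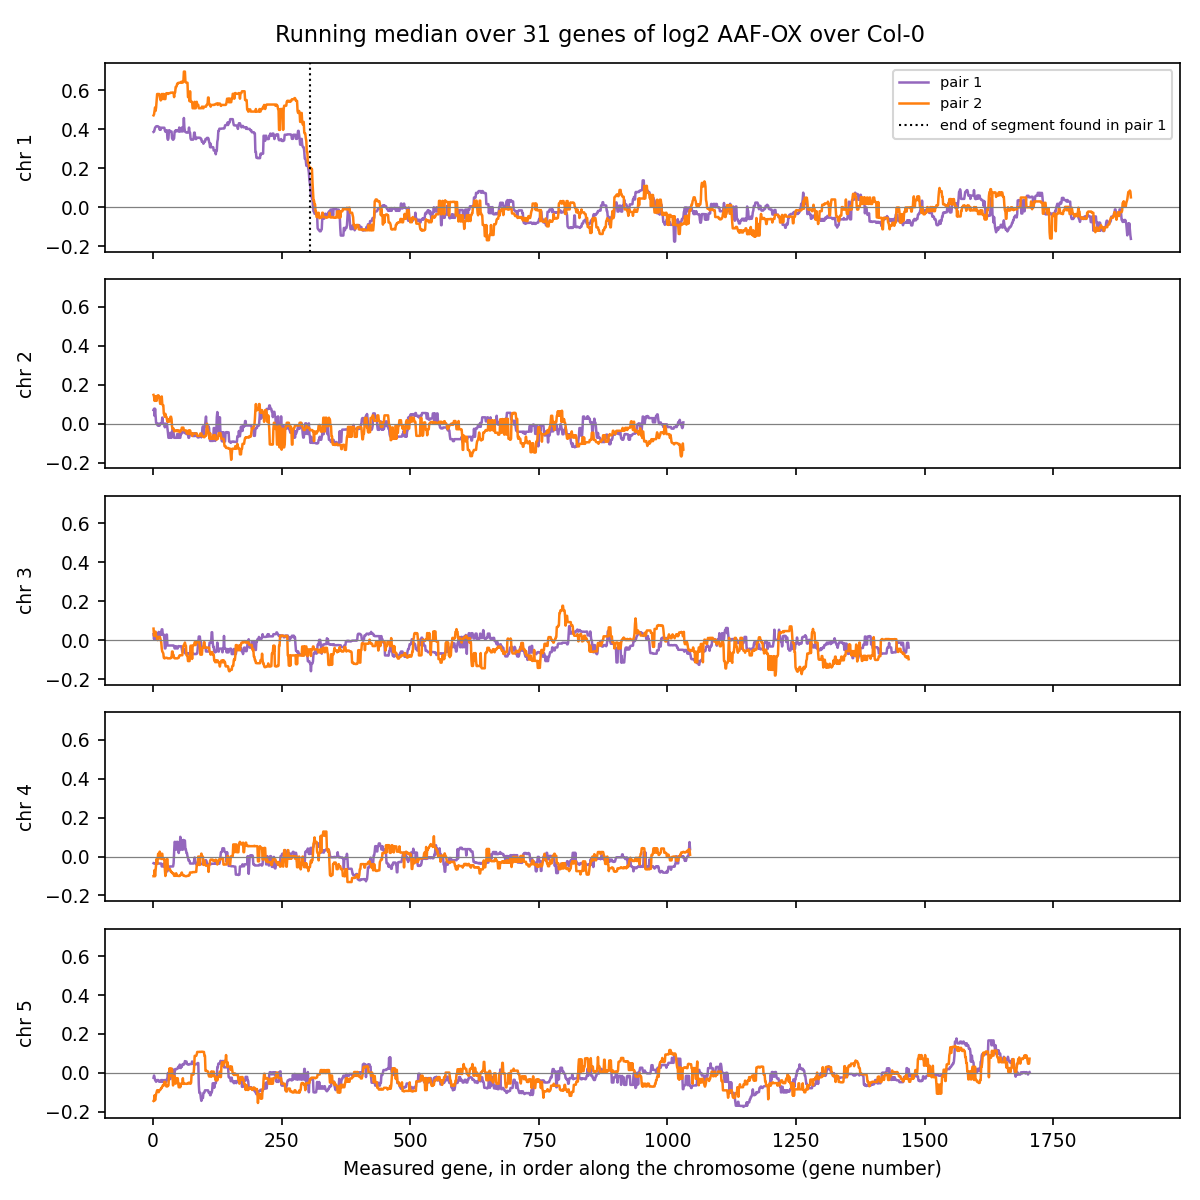
Running median over 31 genes of the log2 difference between AAF-OX and Col-0 (vertical axis, 1 panel per nuclear chromosome) against the number of each measured gene in order along its chromosome (horizontal axis), with 1 line for each pair. The lines of both pairs stay raised over the first 305 genes of chromosome 1, up to the dotted line, and in consecutive windows of 50 genes beyond it the highest median was 0.13 in pair 1 and 0.09 in pair 2, both from AT5G62960 to AT5G64250 on chromosome 5.

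The sets themselves differed far more than the genotypes. Set 2 against set 1, without a genotype term, gave 3996 called probe sets (limma, 1741 higher and 2255 lower in set 2), of which 1105 differed at least 2-fold, and with a genotype term 5350. Higher in set 2 were the clock gene GIGANTEA (GI), at 111.6 and 93.8 in the set 1 arrays and 1937 and 1522 in the set 2 arrays, the thionin gene THI2.2 (log2 3.75), the jasmonate-responsive transcription factor gene ORA47 (3.23) and the methionine sulfoxide reductase gene MSRB6 (3.15). COR15A and COR15B were also higher in set 2 (1.81 and 2.50), as was STZ (2.94). Lower in set 2 were CHI (-3.49), PDF1.2b (-2.99), PDF1.2 (-2.82), COR27 (-2.62) and AT4G16260 (-2.60). Of the 210 probe sets called between genotypes, 129 also differed between sets, so that their levels depend on the set even where both pairs show the same direction. Among all 13592 tested probe sets, 39.36% differed between sets in the fit with a genotype term. The genotype and set contrasts use the same error estimate for each probe set, which favours overlap. The 2 shares therefore do not show that genotype calls depend more on the set than other probe sets do. The set genes were chosen after their values were seen, from the largest differences with a genotype term and from the genes named above.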

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

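The largest dependence is on the design. The replicate block took the calls from 0 to 210 probe sets and from 0 to 41 at 2-fold, and it took AAF, at the same log2 difference of 2.85, past the threshold. It changed no call of a gene list. By the rule of 2-fold in both pairs, without a test, the count was 21, and it was 35 with a pseudocount of 1 and 9 in crossed pairs. Without the block, all other settings and each array left out still called 0 probe sets (limma), and AAF stayed at log2 2.46 to 3.24 with 1 array left out. The photosynthesis list, at 0 lists called in the planned fit, became 1 with the filter at a mean of 250, and leaving out single arrays gave 0 to 1, with 1 without Col-0 replicate 1 and without AAF-OX replicate 2. With an estimated correlation camera gave p = 0.477, 0.531 and 0.333 for these, so none passed. A group left with 1 array was assumed to vary like the other. Leaving out 1 array also mixes the set difference into the genotype difference. With the block and settings added after seeing the data, 210 became 76 with a pseudocount of 1 and 137 with median centring. It became 117 without the named genes of the chromosome 1 segment (fewer genes tested), 18 without the filter and 21 without the intensity trend. At 2-fold, 41 became 18 and 21 in the last 2. The filter at a mean of 250 with the block called 1 list, the photosynthesis genes (camera p = 0.0462, and p = 0.509 with an estimated correlation). The cause of these changes was otherwise not tested. The 76, 137, 117, 18 and 21 calls were all among the 210. For 33 named genes, 249 of 322 values under 10 such settings kept direction and call, 73 kept the direction and lost the call, and 0 reversed. Dim signals limit the lower end, since 30.1% to 31.4% of the values on each array were under 50.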

Other observations

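The patterns and all tests of them here were chosen after the data were seen, and for every test but those of scaling and of signal level the deciding value had been seen too. Several genes outside the naming rule, picked after their values were seen, passed limma's threshold with the sets as a block. SUFE2, which codes for an activator of iron-sulfur cluster assembly in plastids, was higher in AAF-OX (log2 0.98 ± 0.15, adjusted p = 0.00865), at 498.9 and 1126 in pair 1 and 94.5 and 212.1 in pair 2. A second gene of the glutaredoxin family, AT4G15700, was higher by 0.67 (adjusted p = 0.0444), and so were AT1G72900 and AT1G72920, of the TIR-domain family, by 0.74 and 0.70 (adjusted p = 0.0286 and 0.0456). Lower were LCR69, a small cysteine-rich defensin-like gene (-0.68, adjusted p = 0.022), and GH9C2, an endoglucanase family gene (-0.67, adjusted p = 0.0249). SUFE2, AT4G15700, AT1G72900, AT1G72920, LCR69 and GH9C2 were not called without the filter on dim probe sets or without the intensity trend, and the calls of AT4G15700 and AT1G72920 were lost in 5 of 10 alternatives. The largest increase of a called probe set with no gene name here was from 25.2 to 604 in pair 1 and from 68.6 to 746.3 in pair 2 (log2 2.93, adjusted p = 5.11e-06).

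Between sets, the 69 plastid-encoded genes had a median of 0.42 higher in set 2 (camera adjusted p = 6.39e-08 over 32 gene groups with a preset correlation, and adjusted p = 0.967 with an estimated correlation). The other groups, formed by shared symbol stems, can mix unrelated genes and are not reported. The 10 measured neighbours of AT3G02630 had a median log2 difference of -0.19 between genotypes, with a range of -0.49 to 0.14, and those of AT1G66330 had -0.15, with a range of -0.45 to 0.13.

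The first 305 measured genes of chromosome 1 were higher in AAF-OX, by a median of 1.30-fold in pair 1 and 1.45-fold in pair 2, with an end at AT1G11280 in pair 1 and at AT1G11330 in pair 2. A signal level or scaling effect that acts on all genes alike is argued against. Random gene sets of the same size and signal level were drawn from outside the segment. Of 10000 such sets, 0% reached the median of pair 2, and the highest had 0.04. As the stretch was picked for being raised, the draws do not weigh chance. Induction limited to the called genes is argued against too. The 244 genes of the segment that were not called still had a median 0.506 above the rest of the genome in pair 2. Modest induction of many genes there cannot be told apart from a shift of the whole segment. The blocked fit recovered only 36% of simulated changes at a log2 of 0.585, so induced genes can go uncalled. A candidate explanation is a gene dosage difference over 1 chromosome segment between the AAF-OX and Col-0 plants used, as 94.1% of its dim genes, 100% of its genes of middle signal and 98% of its bright genes, in groups of equal size, were higher in pair 2, and the 151 genes with a mean of at least 500 had a median log2 difference of 0.59 in pair 2 and 0.41 in pair 1. A fixed dosage difference would give the same ratio in both pairs, but the medians were 1.30-fold and 1.45-fold, and the reason was not tested. The shares by signal level would also be met by any other rise over the whole segment. The arrays do not measure DNA, the ratio does not tell which line differs from its background, and an effect of AAF on the whole segment was not tested.

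Among the called probe sets, 182 were higher and 28 lower with the sets as a block. Noise in a fit with 1 residual degree of freedom is argued against for the largest increases. Of the 100 largest increases of pair 1, 83% were also higher in pair 2, against 46.8% of all probe sets. It is not argued against for the decreases, where 61% of the 100 largest were also lower, against 53.2% of all. These 100 were ranked in pair 1 alone rather than by the test, so smaller called increases are not covered. In the simulation, 20 of 176 calls of the blocked fit were false. Scaling of the arrays is argued against, since 86.6% of the calls were higher after quantile normalization. Genes of the chromosome 1 segment may account for part of the asymmetry: 62.2% of the named calls outside it were higher. How much of it they account for stays open, because 93 of the higher and 11 of the lower calls have no known place.

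Most variation lay between the sets of arrays. RNA degradation that shifts signal toward the 3' end is argued against, since the log2 ratio of 3' over 5' signal of actin moved by 0.04 from set 1 to set 2 and that of GAPDH by 0.15, while the 25S rRNA control was at 864 and 469 in set 1 and at 186 and 153 in set 2, a difference whose source was not tested. The bacterial poly-A controls dap, thr, phe and lys were at 2.46 to 30.1 in set 1 and at 94.4 to 538 in set 2, which is 10.41-fold, 4.23-fold, 2.78-fold and 2.12-fold on the scale of signal plus 50. Since the pseudocount sets the size of these folds and they may show only that no control was added in set 1, a difference in target preparation that shifted plant transcripts cannot be told apart from differences in growth or harvest. The higher GI level in set 2 leaves a difference in harvest time open, as the labels give none and this was not tested.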
